A study of Homo sapiens with 6 samples.

How the data were processed

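Circular RNAs were measured in 3 infected and 3 uninfected samples of HCT-8 cells at 24 h, 1 array per sample. Per the labels, total RNA was prepared with TRIzol, amplified linearly and labelled with Cy3. Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 11.5.1.1 and hold an intensity for each spot: a background-subtracted, spatially detrended processed signal, pixel medians of spot and local background, and quality flags, with no normalization between arrays. The deposited series matrix holds log2 values of the same probes, which equal the mean log2 processed signal of a probe minus the 75th percentile of the array. The authors' table of competing RNAs gives for each pair a correlation, a score, a p-value and a q-value, and the number and names of shared microRNAs. How these were computed, and the messenger RNA values behind them, are not given in the sources used here. The multiplicity and source of the parasite, the number of separate cultures and the host genes of the circRNAs are not given in the sources used here either.

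Values were computed from the scanner files in R 4.3.3 with limma 3.58.1, version 1.17.8 of data.table and jsonlite 2.0.0. Of 180880 spots, 175906 were not marked as controls, and 110 of these were vector controls that were set aside. Spots marked as outliers were left out, the log2 processed signals of the spots of a probe were averaged, and the 75th percentile over all circRNA probes of the array was subtracted. A total of 5456 probes had 2 spots, and the rest had 1. The percentile signal was 847, 749 and 1042 for infected 1, 2 and 3 and 908, 870 and 1053 for uninfected 1, 2 and 3. Of 170340 circRNA probes (134751 with circBase identifiers and 35589 with hsa-circRNA identifiers), 149514 were well above background on all 3 arrays of at least 1 group. Of these, 533 lacked a value on an array because of outlier spots, and 148981 were tested. The median SD of the spots of 1 probe was between 0.06 and 0.08 on the log2 scale on the 6 arrays.

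Infected and uninfected arrays were compared with limma's lmFit and eBayes (two-sided moderated test, no covariate), with Benjamini-Hochberg adjustment over all circRNAs tested and an adjusted p threshold of 0.05. With 3 arrays against 3, a permutation test can give no p below 0.1, so none is reported per circRNA. Independent normal values were simulated with the means of these circRNAs and their moderated SD from eBayes, which is drawn towards a common value. Of 148981 circRNAs 200 were changed, and no variation was shared between circRNAs. The same steps recovered 84 of 100 changed by 1 and 100 of 100 changed by 2 on the log2 scale, with 17 false calls among 148781. Recovery with the measured spread of each circRNA was not simulated. The well-studied panel was adjusted over the list alone and over all circRNAs tested. GAPDH and PGK1 probes were fitted with the circRNAs and adjusted over those 4 probes. Kinds of identifier were compared with Fisher's exact test. Detection in 1 group alone used the scanner software's call per spot, and folds were taken against the measured signal or the lowest signal called detected on that array, whichever was higher. Against the latter they are lower bounds. Symbols of the authors' table were updated by Entrez identifier with the annotation of assembly GRCh38.p14, used for names alone: 766 of 766 matched and 37 changed.

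The comparisons, the alternatives and the circRNAs to be named were fixed before the data were examined. The rule named the 10 circRNAs with the largest rise and the 10 with the largest fall among those past the threshold, well above background on all 6 arrays and with groups that did not overlap, at most 1 per host gene, or, when nothing passed, those with the smallest unadjusted p. It also named the members of the panel and the 3 circRNAs in each direction with the highest fold in the detection comparison. The parts of the rule that need a host gene could not be applied, since the files give none. For the same reason the common names of panel members are not printed, gene list tests by host gene were not run, and the 23 gene lists were used only to count messenger RNAs of the authors' table. Cell type markers by host gene could not be examined. Other circRNAs are named with a statement that they were picked out after their values were seen.

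Alternatives were quantile normalization, median scaling, cyclic loess, the percentile over probes detected on all arrays, normexp background correction with an offset of 50, the deposited series matrix values, no filter, detection on all 6 arrays, eBayes with trend and robust, an unmoderated test, an unadjusted p with a 2-fold threshold, array quality weights, the replicate number as a block, slide as a block and leaving out each array in turn. Normexp was planned on mean signals, which the files lack, and was run on median signals. A fit within slide 1 and a common detection limit were added after the data were seen. For runs of neighbouring circBase identifiers, identifiers at most 2 apart were joined and compared with 1000 random draws of as many identifiers. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.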

Results

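HCT-8 is a line of human colonic epithelial cells, and Cryptosporidium parvum is a protozoan parasite that infects the epithelium of the gut. Circular RNAs (circRNAs), closed loops made by back-splicing, were measured at 24 h in 3 samples of infected and 3 samples of uninfected HCT-8 cells. Each sample was hybridized to 1 array of 1 colour with 175796 circRNA spots for 170340 circRNA probes. Between 87.0% (infected 1) and 90.8% (uninfected 2) of these spots were well above background, no spot was saturated, and 148981 circRNAs were tested. Pairs of arrays correlated with r between 0.983 and 0.994 across circRNAs, which are not independent replicates. Infected 1 and 2 and uninfected 1 and 2 lay on slide 1, and infected 3 and uninfected 3 lay on slide 2. All values are log2 signals relative to the 75th percentile of the array, every mean is over n = 3 arrays, and the number of arrays limits the precision. The p-values measure only the spread between these samples, since the labels speak of wells and do not state separate cultures. The files give no host gene or position for any circRNA, so circRNAs are named by their identifiers alone.

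The first comparison asked which circRNAs differed between infected and uninfected cells at 24 h. No circRNA passed the test after adjustment for all circRNAs tested. The nearest, with equal adjusted p, were hsa_circ_0020280 and hsa_circ_0031755, higher in infected cells, and hsa_circ_0023308, lower, and of these hsa_circ_0020280 alone was well above background on all 6 arrays. In a block of 10 circRNAs with consecutive identifiers starting at hsa_circ_0139844, infected cells were higher by far more against uninfected 1 and 2 than against uninfected 3.

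In limma, 0 of 148981 circRNAs had an adjusted p under 0.05, and the smallest adjusted p was 0.0804. The count was 24 with array quality weights (18 higher, 6 lower) and 8 with normexp, all higher. An unadjusted p under 0.05 was found for 16893 circRNAs (11.3%), 9303 of them higher and 7590 lower in infected cells. Chance gives 5% on average, and the other splits of the arrays into 3 and 3 gave 0.9% to 9.5%. The side with more circRNAs changed when arrays were scaled by their median (45.2% higher in place of 55.1%), by quantile normalization (46.4%) or by cyclic loess (49.3%). With normexp 65.1% and with no filter on dim probes 64.6% were higher. Of the 16893, 215 were at least 2-fold higher and 51 at least 2-fold lower, a total of 266. This total became 596 without infected 3 (438 higher, 158 lower) and 402 without uninfected 3 (320 higher, 82 lower). It was 94 with normexp (91 higher, 3 lower), 174 with detection on all 6 arrays (163 higher, 11 lower) and 770 with no filter (553 higher, 217 lower). The infected and uninfected values did not overlap for 17.4% of circRNAs, where chance gives 10% on average. The unmoderated test with the same adjustment called 1 circRNA, which was 0.28 higher in infected cells. Leaving out uninfected 3 gave 41 circRNAs past the threshold (32 higher, 9 lower), leaving out infected 3 gave 11, all higher, leaving out uninfected 2 gave 1, hsa_circ_0023308, which was lower, and leaving out any other array gave 0. With slide as a block the count was 0, and within slide 1 it was 27 (24 higher, 3 lower, the latter being hsa_circ_0081566, hsa_circ_0081567 and hsa_circ_0081574). Slide 2 held 1 array of each group and gave folds without a test, and the differences on the 2 slides correlated with r = 0.191 across circRNAs.

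Hsa_circ_0020280 had the smallest unadjusted p of all circRNAs tested. Its log2 signal was -0.31 ± 0.05 (SD, n = 3) in infected and -1.75 ± 0.17 (SD, n = 3) in uninfected cells, a 2.72-fold difference (1.44, SE 0.12, limma adjusted p 0.0804). The difference was 1.37 on slide 1 and 1.58 on slide 2. Its adjusted p was 0.00123 with normexp, 0.00277 with trend and robust, 0.0173 with array quality weights and 0.0415 without uninfected 3. Next among those well above background on all 6 arrays, hsa-circRNA15786-3 was dimmer, at -3.40 ± 0.22 (SD, n = 3) in infected and -4.81 ± 0.04 (SD, n = 3) in uninfected cells, a difference of 1.41 (SE 0.13, limma adjusted p 0.0999). It differed by 1.52 on slide 1 and by 1.17 on slide 2, and its adjusted p was 0.0437 without infected 3. Hsa_circ_0081139 differed by 0.91 on slide 1 and 0.93 on slide 2, from -1.30 in uninfected to -0.39 in infected cells (adjusted p 0.242). Hsa_circ_0076096 was 2.16-fold and hsa_circ_0032056 2.32-fold higher in infected cells, both with an adjusted p of 0.242. The other 5 circRNAs that the rule named as higher in infection, hsa_circ_0050420, hsa-circRNA770-68, hsa_circ_0102294, hsa-circRNA12747-6 and hsa_circ_0117996, were between 1.83-fold and 2.03-fold higher.

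Among circRNAs lower in infected cells, hsa_circ_0058965 had the smallest unadjusted p of those detected on all 6 arrays. It measured -4.72 ± 0.10 (SD, n = 3) in infected and -3.37 ± 0.28 (SD, n = 3) in uninfected cells, a difference of -1.35 (SE 0.15, limma adjusted p 0.226), with -1.56 on slide 1 and -0.92 on slide 2. Without uninfected 3 its adjusted p was 0.0169. Hsa_circ_0107500 followed at -0.89 (SE 0.11, adjusted p 0.242) and hsa_circ_0070181 at -0.97 (SE 0.13, adjusted p 0.285). The 7 others, hsa_circ_0031890, hsa-circRNA10194-23, hsa_circ_0010357, hsa-circRNA11663-2, hsa_circ_0091949, hsa_circ_0033261 and hsa_circ_0070175, differed by -0.89 to -0.65.

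**Figure D1:**
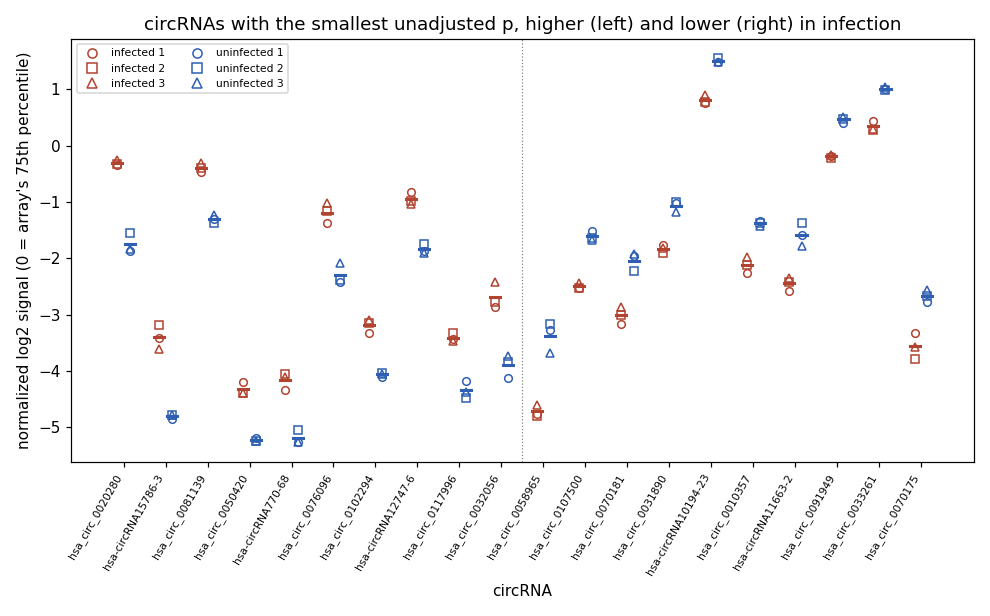
Normalized log2 signal (vertical axis, 0 is the 75th percentile of the array) on each of the 3 infected and 3 uninfected arrays for the 20 circRNAs with the smallest unadjusted p, 10 higher on the left and 10 lower on the right; bars are group means. Infected and uninfected points do not overlap for any of them, by the rule that chose them, and hsa_circ_0020280 differs by 1.44.

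The other circRNAs with the smallest adjusted p of 0.0804 were not well above background on all 6 arrays, and they were picked out after their values were seen. Hsa_circ_0023308 was lower in infected cells by -1.97 (SE 0.17), and without uninfected 2 it passed the threshold with an adjusted p of 0.0453. It was well above background on only 3 arrays. On infected 1, 2 and 3 it read -7.40, -7.56 and -7.36, close to the negative control probes (-7.47, -7.65 and -7.38). Its difference therefore has no exact size. Hsa_circ_0031755 was higher by 1.78 (SE 0.16).

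Many of the largest differences belonged to circRNAs in which 1 array stood apart from its group, and these too were picked out after their values were seen. The 10 circRNAs from hsa_circ_0139844 to hsa_circ_0139853 had group differences of 2.69 to 5.21. Of these, hsa_circ_0139845, hsa_circ_0139848, hsa_circ_0139849 and hsa_circ_0139853 (4.56 to 5.21) were well above background on only 4 or 5 arrays, so their differences have no exact size. Hsa_circ_0139853, the highest, read -7.80 on uninfected 1, where the negative control probes read -7.94. Its difference was 3.16 in the setting where it was lowest. For hsa_circ_0139846 the log2 signals were 2.69, 2.68 and 2.27 on the infected arrays, -4.07 and -3.74 on uninfected 1 and 2 and 1.12 on uninfected 3, so that the difference was 6.59 on slide 1 and 1.16 on slide 2 (adjusted p 0.309). All 10 passed the threshold without uninfected 3 and within slide 1. The 9 circRNAs from hsa_circ_0081566 to hsa_circ_0081574 were lower on the infected arrays than on uninfected 1 and 2, and uninfected 3 lay near the infected level. Of these, hsa_circ_0081574 measured -1.53, -1.74 and -1.56 in infected cells and 0.16, 0.24 and -1.45 in uninfected cells (difference -1.26, adjusted p 0.345), and without uninfected 3 it fell by 1.81 with an adjusted p of 0.00617. In contrast, hsa_circ_0121378 was 5.01 higher in infected cells on slide 1 and 0.40 higher on slide 2, where infected 3 lay close to the uninfected level. It differed by 3.47 over all arrays (adjusted p 0.339) and by 4.99 without infected 3, where its adjusted p was 0.00098. The 7 circRNAs from hsa_circ_0049235 to hsa_circ_0049241 had the same form, with hsa_circ_0049241 at 2.58 and 1.51 in infected 1 and 2, -0.01 in infected 3 and between -0.22 and 0.11 in uninfected cells.

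**Figure D2:**
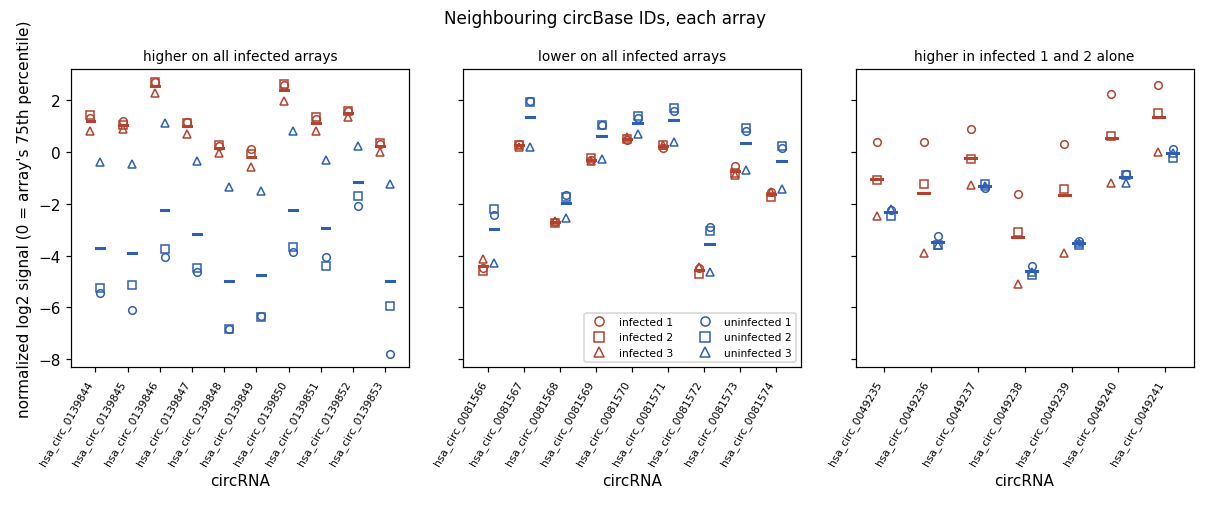
Normalized log2 signal (vertical axis) on each array for circRNAs with neighbouring circBase identifiers, in 3 panels: higher on all infected arrays, lower on all infected arrays, and higher in infected 1 and 2 alone; bars are group means. Uninfected 3 (blue triangle) lies between the groups in the left panel and at the infected level in the middle panel, and infected 3 (red triangle) lies near or below the uninfected level in the right panel.

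The second comparison looked at a fixed panel of 25 well-studied circRNAs, matched by circBase identifier. Of these, hsa_circ_0001946 was the only member past the threshold over the list alone, and it was higher in infected cells, with a wide spread between uninfected arrays. It did not pass over all circRNAs tested.

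The array held all 25 members, and 23 were tested. Hsa_circ_0001946 measured -0.19 ± 0.19 (SD, n = 3) in infected and -3.18 ± 1.41 (SD, n = 3) in uninfected cells, a 7.97-fold difference (2.995, SE 0.56). Its limma p was 0.0118 adjusted over the list alone and 0.307 adjusted over all circRNAs tested. The signal was -3.98 in uninfected 1, -4.02 in uninfected 2 and -1.56 in uninfected 3, and the difference was 3.91 on slide 1 and 1.17 on slide 2. Its p adjusted over the list alone was 0.169 with trend and robust, 0.125 with the unmoderated test, 0.0618 without infected 2 and 0.0531 without uninfected 2, so that the call ended in each. Over all circRNAs tested hsa_circ_0001946 passed without uninfected 3 (3.81, limma adjusted p 9.3e-05) and within slide 1 (3.91, limma adjusted p 0.00045). Hsa_circ_0007444 was 0.47 higher (SE 0.13, p 0.053 adjusted over the list alone), with 0.55 on slide 1 and 0.32 on slide 2, and without infected 3 it passed with 0.0359. Hsa_circ_0001846 (0.24) and hsa_circ_0001313 (0.30) each had a p of 0.304 adjusted over the list alone. Over the 22 members that did not pass, differences ranged from -0.24 (hsa_circ_0007334) to 0.47. Of the members not tested, hsa_circ_0000994 was well above background on none of the arrays and hsa_circ_0000479 on 2 arrays of each group.

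**Figure D3:**
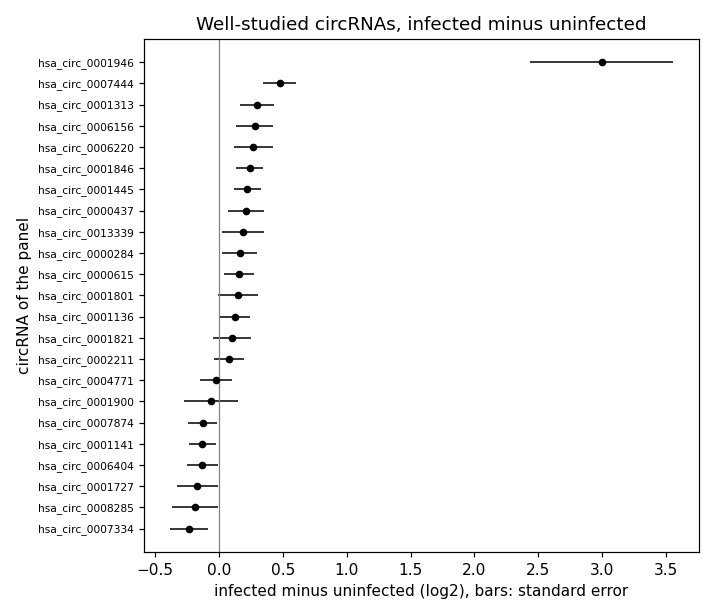
Infected minus uninfected log2 signal (horizontal axis; points are differences of means over 3 arrays per group, bars are standard errors) for the 23 panel circRNAs tested. Hsa_circ_0001946 lies at 2.995, and the others lie between -0.24 and 0.47.

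The third comparison counted circRNAs detected in only 1 of the groups. More circRNAs were detected on the uninfected arrays alone than on the infected arrays alone, but the order turned round when 1 limit was used for every array. Well above background on all 3 arrays of a group and on none of the other were 14 circRNAs for the infected and 379 for the uninfected arrays. Hsa_circ_0060541 was at least 2.78-fold, hsa_circ_0009058 at least 2.75-fold and hsa_circ_0112463 at least 2.67-fold higher on the infected arrays. Hsa_circ_0023818 was at least 1.84-fold and hsa-circRNA6874-14 at least 1.65-fold higher on the uninfected arrays, and hsa_circ_0100501 was 1.85-fold higher as measured, which is not a lower bound. These 6 ranked highest in each direction, and their adjusted p was between 0.156 (hsa_circ_0009058) and 0.322 (hsa_circ_0023818). With a common limit of -5.01 on the log2 scale the counts were 115 for the infected and 68 for the uninfected arrays.

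The fourth comparison asked whether linear messenger RNA differed. The arrays held human probes for GAPDH and PGK1 alone, each near the 3' and the 5' end. None passed the test: in limma 0 of 4 probes had an adjusted p under 0.05, and 0 had an unadjusted p under 0.05. GAPDH differed by 0.09 (SE 0.16) at the 3' and 0.11 (SE 0.15) at the 5' end, and PGK1 by 0.12 (SE 0.17) and 0.07 (SE 0.21), with p between 0.493 and 0.756. On slide 1 PGK1 differed by 0.05 at the 3' end and by -0.09 at the 5' end, and on slide 2 by 0.25 and 0.39. The 3' signal of GAPDH exceeded its 5' signal by 0.55 to 0.65 on the 6 arrays, and that of PGK1 by 2.90 to 2.95 on the infected arrays, by 2.79 on uninfected 1 and 2 and by 3.03 on uninfected 3.

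The fifth comparison set the 2 kinds of identifier on the array against each other. No difference in frequency between the kinds was detected. At an unadjusted p under 0.05 and at least 2-fold were 218 of 116513 circRNAs with a circBase identifier (0.187%) and 48 of 32468 with an hsa-circRNA identifier (0.148%), with a two-sided Fisher's exact p of 0.158. In limma 0 of either kind had an adjusted p under 0.05.

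A deposited table of the authors pairs circRNAs with messenger RNAs that may compete for the same microRNAs. Nearly all of its circRNAs had an unadjusted p under 0.05 here, most with differences under 2-fold. It lists 3354 pairs of 2207 circRNAs and 766 messenger RNAs, with correlations of at least 0.99 and none negative, so that the circRNAs tied to 1 messenger RNA differ in 1 direction by the way they were chosen. Of these circRNAs 2184 were tested, 908 with a higher and 1276 with a lower mean in infected cells, and their median size of difference was 0.38. In limma 0 had an adjusted p under 0.05, 2168 had an unadjusted p under 0.05, and 24 of the latter were at least 2-fold different. The sources used here do not state which samples the table rests on. Across these 6 arrays, circRNAs tied to 1 messenger RNA probe of the table correlated by at least 0.962 in all 8965 pairs. The largest unadjusted limma p of the 2184 was 0.0561. These values argue for a choice made on these same arrays. The table is therefore not taken as independent of the comparison, and the small p-values of its circRNAs add no support. The messenger RNA with most circRNAs was CHMP3, with 25, followed by MTRR with 22 and ST7L with 19. SMAD4 had 17 partner circRNAs, which differed by -0.67 to -0.27. Its TGF-beta list also had NEDD4L (9 circRNAs, -0.56 to -0.29) and SKI (6, -0.64 to -0.29). CYCS (9 circRNAs, 0.28 to 0.79), ELOVL6 (8, 0.28 to 0.69), GBP2 (2, 0.41 to 0.54) and METTL14 (1, 0.45) had partners with higher means. CLDN4 (6, -0.52 to -0.27), CTNNA1 (5, -0.47 to -0.33), STAT2 (1, -0.48) and TAB1 (3, -0.44 to -0.31) had partners with lower means.

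Members of the fixed gene lists in that table were counted by list. Messenger RNAs with partners of lower means alone were counted in the lists of chromatin modifiers (15 of 16 messenger RNAs), actin cytoskeleton (6 of 6), PI3K-AKT-mTOR (5 of 5), Wnt (5 of 5), TGF-beta (3 of 3), cell cycle (3 of 3), lipid and cholesterol uptake (5 of 6), ubiquitin ligases (4 of 5), endocytosis and vesicle traffic (4 of 6), circRNA biogenesis factors (3 of 4), apoptosis (2 of 3), tight and adherens junctions (2 of 2) and NF-kB and Toll-like receptor signalling (1 of 1), with NEDD4L counted in both the TGF-beta and the ubiquitin ligase list. Of all 766 messenger RNAs in the table, 524 were of this kind. Interferon response and autophagy had 1 of 2 each, and glycolysis 0 of 1. The lists of cytokines and chemokines, MAPK, and the epithelial, leukocyte, fibroblast, hepatocyte and neural markers had 0 messenger RNAs in the table. No test was made, since the features that could have entered the table are not given.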

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

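The tests of uninfected 3 and of infected 3 given here were chosen only after the result was seen. The common detection limit was chosen only after the counts per group were seen, and its bound of 3 was written before the counts under that limit were computed.

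Of 79 control probes with a value on every array, the comparisons above tested only the human GAPDH and PGK1 probes. The negative control probes served as a reference for dim signals. Among the 79, 8 read higher on every infected array than on every uninfected array and 0 read lower on every infected array. The human GAPDH and PGK1 probes were not among the 8. The 8 were picked because they lay outside the circRNA comparison and their groups did not overlap. All 8, among them the dark corner spots (0.38 higher), lay at or below -7.13 on the log2 scale, and their differences were 0.19 to 0.44. Chance gives 10% of probes with groups apart in either direction, about the share of 8 in 79, so no difference beyond chance was shown.

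More circRNAs were detected on the uninfected arrays alone (379) than on the infected arrays alone (14). With 1 common limit for all arrays the counts were 68 and 115, a ratio of 0.591, against a bound of 3 for an excess that was not due to the limit. The ratio lay on the side set for a difference in the detection limit of each array. The common limit of -5.01 lay above most undetected signals, however, and at most 68 of the 379 were counted under it. The counts therefore cannot decide whether detection limits gave rise to the excess. As measured, the 379 differed by a median of -0.50 on the log2 scale. Whether the background itself differed between the groups beyond chance was not tested.

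In 64 circRNAs all infected arrays lay at least 1 above uninfected 1 and 2 on the log2 scale, among them the 10 from hsa_circ_0139844 to hsa_circ_0139853 and hsa_circ_0001946. Uninfected 3 lay above uninfected 1 and 2 in 59 of these and below all infected arrays in 60, a median share of 0.376 (quartiles 0.24 and 0.484) of the way to the infected mean on the unlogged signal and 0.647 (quartiles 0.399 and 0.757) on the log2 scale, which speaks against infection alone and against a wrongly labelled infected array as the single cause. Infected 3, on the same slide, departed from infected 1 and 2 by a median of -0.20 against 1.16 for uninfected 3. The choice of these 64 held infected 3 high and left uninfected 3 free, so this cannot decide whether the slides differed. RNA of infected 3 mixed into uninfected 3 may remain as a cause, but the test could not decide it. The share of 0.43 was fitted to these same 64 circRNAs, so a close match was partly built in. Of the 64, 9 departed from such a mixture by over 0.5 on the log2 scale, against 7 in which uninfected 1 and 2 differed by as much. With the infected mean as the source 17 did. In 15 circRNAs lower on all infected arrays than on uninfected 1 and 2, the median share in uninfected 3 was 0.953 (quartiles 0.741 and 0.979, unlogged). That is near the infected level, as a wrong label would give for these alone, but it rested largely on the run from hsa_circ_0081566 to hsa_circ_0081574. In the 8 outside that run the median share was 0.741 (quartiles 0.449 and 0.825). Of the 15, 11 departed from the same mixture (4 of the 8 outside the run), against 1 in which uninfected 1 and 2 differed by as much. Mixing at that share by itself therefore gave no match for these. The choice of the 15 left uninfected 3 free, however, which may draw it towards the infected level. With uninfected 1 or uninfected 2 left free instead, 3 and 2 circRNAs were chosen, with median shares of 0.310 and 0.586. Part of the departure may thus come from the choice. A difference between the uninfected cultures may remain and was not tested.

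In 161 circRNAs infected 1 and 2 lay at least 1 above uninfected 1 and 2. In 78 of these infected 3 lay under 0.25 of the way on the unlogged signal. Among them were hsa_circ_0121378 and 6 of the 7 from hsa_circ_0049235 to hsa_circ_0049241. In these 6 infected 1 also lay above infected 2, with mean log2 signals of 0.71, -0.78 and -2.77 in infected 1, 2 and 3. Infected 1 lay above infected 2 too in the circRNAs of the 78 with the largest differences on slide 1. Of these, hsa-circRNA12681 read 1.14, -1.45 and -4.00 in infected 1, 2 and 3. The pattern was thus graded over the infected arrays and highest in infected 1. Infected 1 had the lowest array quality weight of all arrays (0.47). It also lay apart on the first principal component, at -96.8, with the other arrays between -29.6 and 38.2. In another 43 of the 161, infected 3 lay over 0.75 of the way. Among circRNAs at least 4-fold higher on slide 1 the quartiles of this share were 0.81 apart, where uninfected RNA in infected 3 or a wrong label would give 1 share for all. Uninfected 3 departed from uninfected 1 and 2 by a median of 0.00525 on the log2 scale in the circRNAs that infected 3 lacked, which speaks against signal lost on slide 2. A response that differed between infected samples may remain and was not tested.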

How the results depend on the processing

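The fit within slide 1 and the common detection limit were chosen only after the result was seen.

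The count of 0 circRNAs past the threshold stayed at 0 with quantile normalization, median scaling, cyclic loess, the other percentile set, the deposited series matrix, no filter, detection on all 6 arrays, the replicate block (0) and the slide block (0). It was 8 with normexp on median signals, 1 with trend and robust (hsa_circ_0020280), 1 with the unmoderated test, 24 with array quality weights and 27 within slide 1. At an unadjusted p under 0.05 and at least 2-fold it was 266, against 131 unmoderated, 94 with normexp, 174 detected on all 6 arrays, 770 with no filter, 772 within slide 1, 402 without uninfected 3 and 596 without infected 3, and those higher outnumbered those lower in every setting. Leaving out 1 array gave 0 to 41, with 41 without uninfected 3, 11 without infected 3 and 1 without uninfected 2. At least 2-fold changed circRNAs numbered 5, 1, 0, 18 and 27 under those settings and 0 to 41 with 1 array left out. Of the 27 circRNAs called within slide 1, 25 were also called without uninfected 3, while of the 11 called without infected 3 none was. The cause of the changes was not tested beyond the tests of uninfected 3 and infected 3 given earlier.

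Panel members past the threshold over the list alone numbered 1, against 2 with cyclic loess, normexp, detection on all 6 arrays or the replicate block, 3 with array quality weights, 0 with the unmoderated test and 0 to 2 with 1 array left out. With trend and robust 1 passed, hsa_circ_0007444 in place of hsa_circ_0001946. The cause was not tested. For hsa_circ_0001946 the difference ranged from 2.37 to 3.91 and the p over the list alone from 1.87e-07 to 0.169. GAPDH and PGK1 gave 0 under every alternative, and the kinds of identifier gave 0 differences. CircRNAs detected in 1 group alone numbered 393, against 1525 for 2 of 3 arrays and 183 with the common limit. Of the authors' circRNAs 24 met the unadjusted p and 2-fold.

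Of 514 values of the 26 circRNAs named by rule, 493 kept their direction and side of the threshold and 21 passed it, 0 reversed. For hsa_circ_0020280 the difference was 1.33 to 1.54 and the adjusted p 0.00123 to 0.421, for hsa-circRNA15786-3 the difference was 0.74 to 1.52 and for hsa_circ_0058965 it was -1.56 to -0.39. Of 460 panel values 447 were alike, 8 passed, 4 no longer passed and 1 near 0 changed sign. Of 1355 values of the 68 circRNAs singled out after their values were seen or with the largest differences, 34 passed and 0 reversed.

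Replicate numbers were not treated as pairs in the main fit. Deviations from the group means correlated by 0.168, 0.0819 and 0.258 for like-numbered arrays and by -0.297 to 0.140 for unlike-numbered ones. These values do not exclude a pairing. With the replicate number as a block, 0 circRNAs passed the threshold. The test of each probe on its own was not run, since each circRNA had 1 probe, and neither were gene list tests. Signal over background limits the dimmest 10% of circRNAs, which held 125 of the 266.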

Other observations

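The counts of splits of the arrays, and the comparison of neighbours between single arrays, were chosen only after the result was seen. The likeness of neighbours had also been seen when its test within groups was written, and only the values within groups had not.

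The 6 arrays can be split into 3 and 3 in 10 ways, which are too few for a share under 0.05. All 10 gave 0 circRNAs past the adjusted threshold, at any fold, at least 2-fold and among the GAPDH and PGK1 probes, so the real value was 0 and the highest other 0. At an unadjusted p under 0.05 and at least 2-fold the real split gave 266 and the highest other 181, and at an unadjusted p alone 16893 and 14155, so 1 split of 10 was as large in each. Panel members past the threshold over the list alone numbered 1 in the real split and at most 0 in the others. For circRNAs detected in 1 group alone the real split gave 393, and the highest other 408 when infected 1, infected 3 and uninfected 3 were set against the rest, so 2 splits were as large.

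Differences between infected and uninfected cells were alike in circRNAs with consecutive circBase numbers, with a correlation of 0.475 over 102467 neighbouring pairs, against at most 0.00993 in 1000 shuffles of the numbers. The hypothesis that infection adds to this likeness was tested against differences within a group. The highest correlation between 2 arrays of 1 group was 0.371, below the median of 0.384 for the 9 single infected arrays against single uninfected arrays, which ranged from 0.279 to 0.426. Other splits into 3 and 3 gave 0.202 to 0.399. This is consistent with a small part of the likeness going with infection, while much of it is also present within groups. Whether neighbours share a host gene, or parts of a probe's target, may explain the rest but was not tested, since the files give neither genes nor sequences.

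Among the 58 circRNAs with circBase numbers that lay higher on all infected arrays, the longest run of neighbours had 10 members, from hsa_circ_0139844 to hsa_circ_0139853, where the longest in 1000 random draws of as many identifiers had 2. Among the 218 with an unadjusted p under 0.05 and at least 2-fold, a further run of 10 lay between hsa_circ_0080898 and hsa_circ_0080911, which held 13 tested circRNAs, and its members differed by a median of 1.12, where random draws gave at most 3. Both runs were picked out after their values were seen. Neighbours were also alike within groups (0.145 to 0.371), which random draws of single identifiers leave out. Runs longer than in the draws therefore do not show a part played by infection.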
